A study of Carex littledalei with 18 samples.

How the data were processed

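Leaves of 18 samples were studied, 3 at each of 6 times at -5 °C. Per the labels, leaves were frozen on dry ice, RNA was extracted with Trizol, and 2 µg of total RNA went into MGIEasy mRNA libraries sequenced by BGI-seq. Reads were trimmed with Trimmomatic 0.36 and inspected with FastQC, per the submitters' processing notes. The aligner, the counting tool and any genome build are not given in the sources used here. The row identifiers are those of a Trinity assembly, in which a gene is a cluster of assembled transcripts and a component is a set of such clusters. Copies, alleles and fragments of one plant gene can therefore stand as several rows.

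The authors deposited a table of estimated counts per assembled gene (expected counts, given to 2 decimals and not scaled between libraries). The authors also deposited a signal table of the same genes and libraries, scaled for gene length and by TMM (trimmed mean of M-values, a correction for library composition) per its name; whether its unit is TPM or FPKM is not stated. Columns were matched to samples by the sample titles, and 0 columns were left unmatched. Library totals were 18895399 to 32345479 counts. For tests, the estimated counts were rounded to whole numbers.

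All 153 pairs of columns were compared. The columns of 0 h replicate 1 and 4 h replicate 1 were equal in all 214531 rows of both tables, with the same total of 28346949 counts. The 2 columns hold 1 set of values under 2 times, and the time of that set was not inferred from its values. The design fixed before the data were examined had used all 18 libraries. It was changed, before any test was run, to leave out both columns, so that 16 libraries were fitted with 2 at 0 h and 2 at 4 h. Fits with all 18, with the library at 0 h alone and with it at 4 h alone were added as alternatives after the data were seen.

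Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 6 times, TMM factors, and the quasi-likelihood F test in 1 model with a mean per time and no covariate, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The SE printed beside a log2 fold change is its absolute value divided by the square root of its F statistic. It is back-calculated from the test and is not a fitted standard error. Of 214531 genes, 68030 were tested. The common biological coefficient of variation was 69.3%, with 10 residual degrees of freedom. Each time was compared with 0 h and with the time before, 24 and 48 h were also compared with 4 h, and all times were tested together. All called genes of the pairwise comparisons differed by at least 2-fold. Levels are CPM, counts scaled to the library total and its TMM factor, as mean ± SD. Where all libraries of a group had 0 reads, a fold was bounded with 3 counts over the group, which covers counting error only. The share of counts in the 100 most abundant genes and the genes detected were tested by permuting times (two-sided by construction, 1e+05 resamples), and profiles by 20000 permutations of a variance partition on log CPM.

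The files do not pair identifiers with gene names, and no reference was used, so the 15 gene lists fixed beforehand were not run. The rule fixed beforehand for identifiers to print took them from genes changed in one direction at 4, 12, 24 and 48 h with a mean log2 CPM of at least 5; it gave 0 genes. The 4 identifiers printed were therefore chosen after values were seen: the 2 late genes of highest mean abundance and the 2 genes of highest mean abundance among those lower at 48 h.

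The procedure was tested on simulated counts of 68030 genes for 48 h against 0 h. Rises of 4-, 16-, 64- and 256-fold were given to 50 genes each, all with a mean of at least 10 reads. No falls were simulated. The procedure recovered 4%, 40%, 92% and 90% of the changed genes, and called 3 unchanged genes. With the changed genes placed at 4 h it recovered 2%, 40%, 64% and 90% for 4 h against 0 h and 6%, 48%, 86% and 94% for 4 h against 0.5 h, and called 0 unchanged genes in either. Alternatives fixed beforehand were RLE size factors, library size alone, DESeq2 1.42.0, limma 3.58.1 on log2(value + 1) of the scaled table, no filter, a filter of 1 CPM in 3 libraries, a 2-fold minimum, an adjusted p of 0.01, fits of only the times compared, the replicate number as a block, and leaving out each library. Added after the data were seen were robust shrinkage and counts summed over components, beside the fits of the identical library.

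Each time was a separate pot, so time and pot cannot be told apart. No plants kept warm for the same time were included, so cold also cannot be told apart from the move or the time passed. The labels do not say whether replicates were separate plants. In either case p-values measure only the spread between samples of 1 pot. If replicates were not separate plants, that spread may be technical. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1.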

Results

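Kobresia littledalei (Carex littledalei) is a sedge of alpine grassland. Plants taken from Tibetan field sites were kept in pots at 25 °C for 7 days and then moved into a room at -5 °C. Leaves were collected after 0, 0.5, 4, 12, 24 and 48 h in the cold, and polyadenylated RNA was sequenced. Each time point had 3 libraries, 18 in all, and each pot was used for 1 time point only. The count table held 214531 assembled genes and between 18895399 and 32345479 counts per library. The library given as 0 h replicate 1 and the library given as 4 h replicate 1 had identical values in all 214531 rows. Because nothing in the labels says which time those values belong to, both columns were left out. The values below come from 16 libraries: 2 at 0 h, 2 at 4 h and 3 at each other time. The files do not pair the assembly's identifiers with gene names, so genes are described as groups and 4 of them are printed by identifier.

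The first comparisons ask which transcripts changed soon after the move to -5 °C. After 0.5 h, 2 genes had risen and 2 had fallen against 0 h, of 68030 tested with edgeR. These 4 were described after their values were seen. One of the genes that rose went from 0.245 ± 0.13 CPM (counts scaled to the library total; SD, n = 2) to 12.7 ± 3 CPM (SD, n = 3), and its mean lay between 0.253 and 0.892 CPM at the later times. The other went from 0.0529 ± 0.02 (SD, n = 2) to 34.2 ± 18 CPM (SD, n = 3) and lay at or below 0.223 CPM later. The genes that fell went from 23.9 ± 24 to 0.0393 ± 0.015 CPM and from 14.5 ± 11 to 0.204 ± 0.16 CPM (SD, n = 2 and n = 3), were still at 0.387 and 0.34 CPM at 4 h, and stood at 115 and 20.2 CPM at 48 h. Both of these were higher again at 24 or 48 h than at 4 h in the direct contrasts. They were the only genes of the 16-library fit to meet the fixed definition of early transient genes. That definition asks for a call against 0 h at 0.5 or 4 h and none at 24 or 48 h. It also asks for an opposite call at 24 or 48 h against 4 h. The 2 genes that rose had already fallen back by 4 h, so it did not count them. Adjusted p-values of the 4 genes in edgeR's quasi-likelihood test were between 0.039 and 0.048. The calls at 0.5 h depended on single libraries: 0 genes were called without 0 h replicate 2, 0.5 h replicate 1 or 2, 4 h replicate 2 or 3, 24 h replicate 1 or 3, or 48 h replicate 1 or 2, and 7 and 8 without 12 h replicates 1 and 3. With all 18 libraries 3 were called, all higher, with the identical library kept at 0 h alone 30 (17 higher, 13 lower) and with it at 4 h alone 0. DESeq2 called 233, a fit of the 0 and 0.5 h libraries only 0, and without a composition factor in the scaling 2 were higher and 9 lower.

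At 4 h no gene passed the threshold against 0 h in edgeR (0 of 68030, with 3367 at an unadjusted p under 0.05), or against 0.5 h (0, with 5248). Among unchanged genes, a share of 0.05 is expected under that p. The 3367 were about that share of the 68030, and the 5248 were above it. DESeq2 called 163 genes at 4 h against 0 h and 495 at 4 h against 0.5 h, and limma on the authors' scaled table called 11 and 165. DESeq2 gave no adjusted p for 28170 and 25557 of the 68030 genes in these comparisons, so it adjusted over fewer genes than edgeR. For 4 h against 0.5 h, edgeR called 98 in a fit of only those times, 4 with all 18 libraries, 3 with the identical library at 4 h alone, 2 without 24 h replicate 1 and 1 with library size alone. Without a filter it called 962 at 4 h against 0 h and 1274 at 4 h against 0.5 h. Counts of 68030 genes were simulated with the spread of these libraries. Rises, and no falls, were placed in genes with a mean of at least 10 reads. For 4 h against 0 h, 4-, 16- and 64-fold rises were recovered in 2%, 40% and 64% of cases. For 4 h against 0.5 h these shares were 6%, 48% and 86%.

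Between 4 and 12 h in the cold, a small group of transcripts rose to high abundance. At 12 h, 15 genes were higher than at 0 h and 0 were lower, and against 4 h 26 genes were higher and 0 lower. Fits of only the libraries of the times compared called 0 genes at 12 and at 24 h against 0 h and 0 at 12 h against 4 h. All 15 were also among the 22 genes higher at 24 h, when again 0 were lower, and 14 were higher at 12, 24 and 48 h. In the 26 genes higher at 12 h than at 4 h, the median of the mean levels was 0.904 CPM at 0 h, 0.229 at 0.5 h and 0.484 at 4 h, and then 49.1 at 12 h, 76.7 at 24 h and 45.5 at 48 h. Their 0 h means reached up to 37.5 CPM, and their median log2 fold change at 4 h against 0 h was -1.49 with the 5 genes that had 0 reads in all libraries of one of these times at their bounds, and 0 were called lower there. At 12 h against 0 h 11 of the 26 were called higher, and the median log2 fold change of all 26 was 5.05, with or without the 2 such genes at their bounds.

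**Figure D1:**
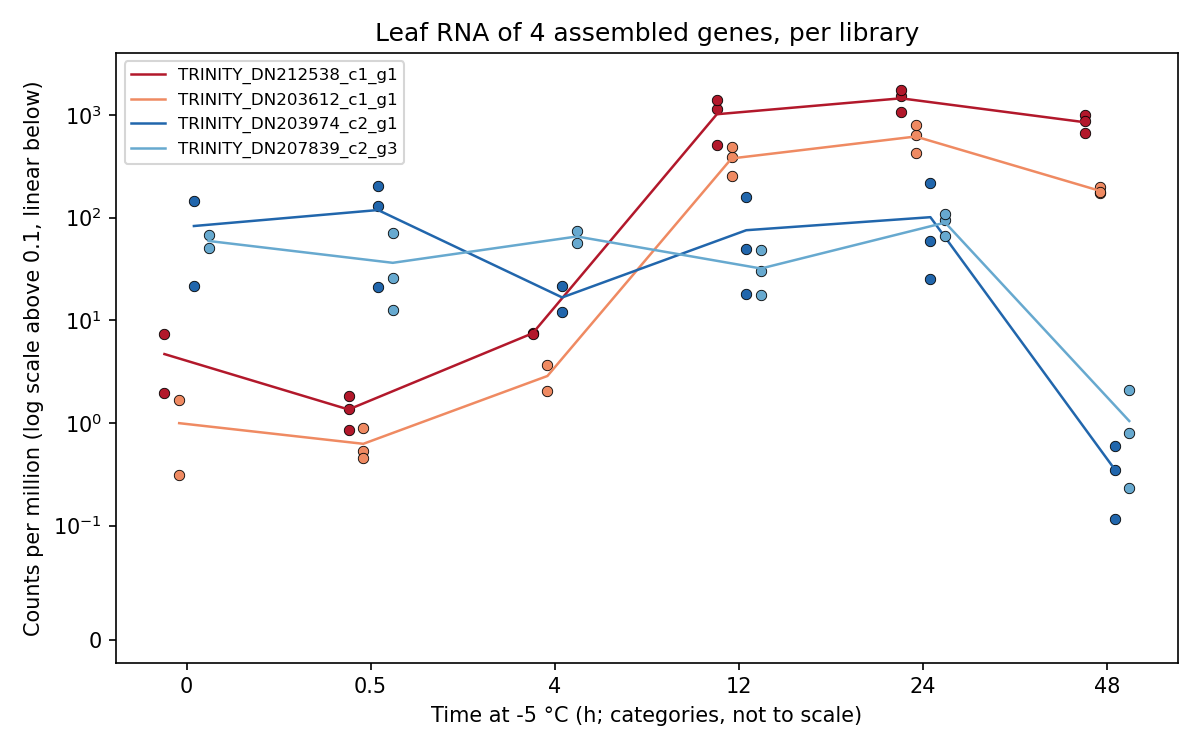
Level of 4 assembled genes in CPM (log scale above 0.1 CPM, linear below) against time at -5 °C in hours; each point is 1 of 16 libraries and lines join the means of each time. The genes TRINITY_DN212538_c1_g1 and TRINITY_DN203612_c1_g1 stayed at or below 7.58 CPM in every library up to 4 h and at or above 173 CPM from 12 h on; the other 2 genes were at or below 2.1 CPM in every 48 h library.

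The most abundant of these late genes was TRINITY_DN212538_c1_g1. It stood at 4.68 ± 3.8 CPM at 0 h (SD, n = 2), 1.35 ± 0.5 CPM at 0.5 h (n = 3) and 7.47 ± 0.16 CPM at 4 h (n = 2). It then reached 1010 ± 460 CPM at 12 h, 1450 ± 340 CPM at 24 h and 846 ± 170 CPM at 48 h (SD, n = 3 each). Its log2 fold change against 0 h was 7.76 at 12 h (SE 0.86, back-calculated from the F statistic, edgeR adjusted p = 0.0014). It was 8.28 at 24 h (SE 0.88, adjusted p = 0.00082) and 7.51 at 48 h (SE 0.85, adjusted p = 0.0019). TRINITY_DN203612_c1_g1 went from 0.995 ± 0.97 CPM at 0 h (SD, n = 2) to 376 ± 120 CPM at 12 h, 615 ± 190 CPM at 24 h and 182 ± 12 CPM at 48 h (n = 3 each). Its log2 fold changes at those times were 8.60, 9.31 and 7.56 (edgeR adjusted p = 0.00068, 0.00034 and 0.0014). Without 0 h replicate 3, the adjusted p of TRINITY_DN212538_c1_g1 was 0.1, 0.059 and 0.062 at 12, 24 and 48 h, with log2 fold changes of 7.15, 7.65 and 6.90. In edgeR fits of only the times compared, its adjusted p was 0.55 at 12 h and 0.23 at 24 h, and that of TRINITY_DN203612_c1_g1 0.46 and 0.22; their log2 fold changes there were 7.78 and 8.28, and 8.61 and 9.30.

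In all, 14 genes in 9 assembly components (sets of transcripts that the assembler linked by shared sequence) met the fixed definition of late genes: higher than 0 h at 24 and 48 h, not called at 0.5 or 4 h, and higher at 48 h than at 4 h. Their median log2 fold change against 0 h was 7.73 at 12 h, 8.30 at 24 h and 7.49 at 48 h. For 3 of them all 0 h libraries had 0 reads, and with these at their lower bounds the medians were 7.53, 8.14 and 7.45. The median of their mean levels was 0.347 CPM at 0 h, 0.746 CPM at 4 h, 49.1 CPM at 12 h, 67.6 CPM at 24 h and 49 CPM at 48 h. Genes of a component share sequence and reads could be divided among them, so the 14 are not independent transcripts. Without either 4 h library, 0 genes were called at 12 h against 4 h and 0 met the late definition; 12 h against 4 h gave 70 and 11 without 12 h replicates 1 and 2. Against 0 h, 12 and 24 h gave 9 and 10 without 0 h replicate 2 and 2 and 3 without 0 h replicate 3, with 9 and 3 late genes, 12 h gave 30 without 12 h replicate 3, and there were 9 late genes without 48 h replicate 2. With all 18 libraries the counts were 25 at 12 h, 40 at 24 h and 26 late genes, and all 14 late genes were called at 24 and 48 h there. With the identical library at 0 h alone they were 34, 55 and 25, with it at 4 h alone 14, 18 and 16, and in DESeq2 371, 367 and 88.

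No gene was called between 12 and 24 h in edgeR (0 of 68030, with 2019 at an unadjusted p under 0.05). The 2019 were fewer than the share of 0.05 expected among unchanged genes. DESeq2 called 24 and limma 0, and edgeR 3 without 12 h replicate 3 and 4953 without a filter. The median log2 fold change of the 14 late genes from 12 to 24 h was 0.60, and 0 of them passed the test for that step. By the fixed definitions, 0 genes peaked at 12 h (11 in DESeq2, 0 in limma, 3 without 12 h replicate 3, 258 without a filter) and 0 were changed in one direction at all of 4, 12, 24 and 48 h (10 in DESeq2, 5 in limma).

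At 48 h a set of transcripts present at the earlier times was nearly absent. Against 0 h, 27 genes were higher and 26 lower. The 26 lower genes lay in 24 components, and the median of their mean levels was 5.71 CPM at 0 h, 4.95 at 0.5 h, 3.87 at 4 h, 5.43 at 12 h and 5.74 at 24 h, but 0.082 CPM at 48 h. Their median log2 fold change at 48 h against 0 h was -6.30, or -5.75 with the 8 genes that had 0 reads in all 48 h libraries at their bounds. TRINITY_DN207839_c2_g3 had 59.1 ± 12 CPM at 0 h (SD, n = 2), 89.3 ± 22 CPM at 24 h and 1.04 ± 0.96 CPM at 48 h (n = 3 each), with a log2 fold change of -5.82 (SE 0.83, edgeR adjusted p = 0.011). TRINITY_DN203974_c2_g1 had 82.7 ± 87 CPM at 0 h (SD, n = 2), 101 ± 100 CPM at 24 h and 0.355 ± 0.24 CPM at 48 h (n = 3 each), with a log2 fold change of -7.84 (SE 1.3, edgeR adjusted p = 0.041). The call on TRINITY_DN203974_c2_g1 was lost without 0 h replicate 2 (log2 fold change -5.90, adjusted p = 0.46), 4 h replicate 2 (-7.79, 0.11) or 48 h replicate 1 (-7.44, 0.22), among other settings. That on TRINITY_DN207839_c2_g3 was lost without 0 h replicate 2 (-5.61, 0.12), 0 h replicate 3 (-5.95, 0.1), 48 h replicate 1 (-5.35, 0.054) or 48 h replicate 2 (-5.66, 0.11).

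Of the 27 genes higher at 48 h, 17 were also higher at 24 h and 10 were called at 48 h alone. The median of the mean levels of those 10 was 0.21 CPM at 0 h, 0.903 CPM at 24 h and 13.6 CPM at 48 h, and 5 of them also passed the test of 48 h against 24 h. Comparisons against 0 h share their 0 h libraries. Unchanged groups simulated against the same libraries had 0 calls at 24 h and 0 at 48 h in 5 draws, so the 0 calls they shared could not have been otherwise. Independent lists of these sizes would share 0.00873 genes. Fold changes at 24 and 48 h had a correlation of 0.506 across genes, against 0.65 in the simulated unchanged groups, and a covariance of 1.83 against 1.33. The 2 libraries at 0 h were not divided, as that would leave 1 on each side, so part of the overlap may come from the shared libraries. The count at 48 h against 0 h was 124 with all 18 libraries (74 higher, 50 lower), 200 with the identical library kept at 0 h alone (125 higher, 75 lower) and 37 with it at 4 h alone (22 higher, 15 lower). It was 1122 in DESeq2, 229 in a fit of the 0 and 48 h libraries only, 14 without 0 h replicate 2, 12 without 0 h replicate 3, 31 without either 4 h library, and 20, 21 and 26 without 48 h replicates 1, 2 and 3. The 17 shared genes were 9 and 3 without 0 h replicates 2 and 3.

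**Figure D2:**
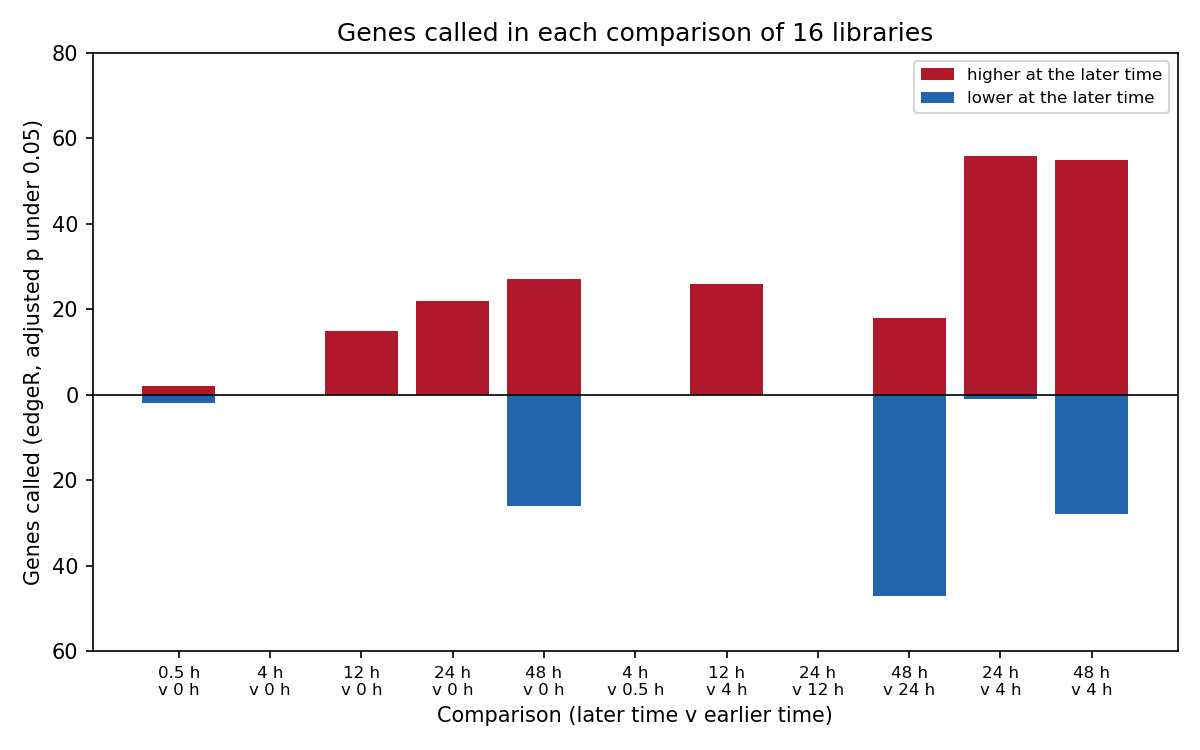
Number of genes called higher (bars above 0) or lower (bars below 0) at the later time of each comparison, by edgeR at an adjusted p under 0.05 in 16 libraries. The most genes were lower at 48 h against 24 h (47) and higher at 24 h against 4 h (56), and 0 were called at 4 h against 0 h, 4 h against 0.5 h and 24 h against 12 h.

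The step from 24 to 48 h was tested directly. In it 18 genes rose and 47 fell. The 47 that fell had a median of mean levels of 7.02 CPM at 24 h and 0.181 CPM at 48 h, and 21 of them were also lower at 48 h than at 0 h. The 18 that rose went from 0.583 to 12.4 CPM by the same measure. Without 24 h replicate 2, a library described further on, 1 gene rose and 17 fell, all 18 of them among the 65. Without 48 h replicate 1, 2 or 3 in turn, 10, 11 and 11 genes were called, and without either 0 h or either 4 h library 26 were called. The count was 164 without 12 h replicate 1 and 34 and 39 without 24 h replicates 1 and 3. It was 42 with the identical library at 4 h alone, 1660 in DESeq2 and 563 in a fit of the 24 and 48 h libraries only.

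Across the 6 times together, 488 genes changed in edgeR's test of all times at once (8299 at an unadjusted p under 0.05). The highest mean of log2(CPM + 0.1) was at 48 h in 177 of them and at 24 h in 166, at 0.5 h in 89, at 12 h in 40, at 4 h in 9 and at 0 h in 7. Over the 68030 tested genes as a whole, 15.5% had their highest mean at 0 h, 20.7% at 4 h and 19.8% at 48 h. Of the 488 the shares were 1.43%, 1.84% and 36.3%. The lowest shares were at 0 and 4 h, the times with 2 libraries each, and whether group size lowers them was not tested. Which genes are switched on or off was asked separately: 11 called genes had 0 reads in all libraries of one time and at least 10 in all libraries of the other. The count of 488 was 133 without 4 h replicate 3, 141 without 4 h replicate 2, 149 and 154 without 0 h replicates 3 and 2, 258 without 0.5 h replicate 2, 274, 251 and 252 without 48 h replicates 1, 2 and 3, and 757 without 12 h replicate 1. The 11 switched genes were 4 and 2 without 0 h replicates 2 and 3, and 5 and 7 without 48 h replicates 1 and 2. The count over all times was 582 with all 18 libraries, 770 with the identical library kept at 0 h alone, 416 with it at 4 h alone, 3502 in DESeq2 and 948 in limma. Without a filter, of 202727 genes tested 15362 were called over all times, and 795, 1050, 2711 and 1771 at 0.5, 12, 24 and 48 h against 0 h. Of the 15362, 7183 were among the 68030 genes tested with the filter, and these included all 488. The added calls therefore did not come from added genes alone.

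The share of the most abundant transcripts and the number of genes detected showed no detectable difference between times, whereas whole expression profiles differed. The 100 most abundant genes held 27.5% ± 5.1 of counts at 0 h (SD, n = 2), 31.7% ± 5.2 at 4 h (n = 2) and 27.4% ± 4.2 at 48 h (n = 3), with a permutation p of 0.92 over the 6 times. The number of genes detected at 1 CPM gave a permutation p of 0.97. In these profiles, time accounted for 41.9% of the variation between the 16 libraries where 33.3% is the chance share (permutation p = 0.0052). Each time was 1 pot, so that share may hold differences between pots. Without the 48 h libraries the share was 37.9% (permutation p = 0.1). Rank correlation between libraries had a median of 0.849 over 14 pairs of the same time and 0.816 over 106 pairs of different times. The ranges overlapped, at 0.803 to 0.912 and 0.762 to 0.92, and the highest value came from a pair of different times. Within a time the rank correlation was 0.912 in the 1 pair at 4 h, and medians over 3 pairs ran from 0.811 at 12 h to 0.882 at 48 h.

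A single library stood apart in the number of genes read almost only in it. In 24 h replicate 2, 17986 assembled genes had at least 90% of all their reads, and these held 6.01% of its counts. The next highest number was 1475, in 12 h replicate 2, and 12 h replicate 1 had 712 such genes with 4.07% of its counts. In 24 h replicate 2, 5.70% of counts fell on genes that did not enter the tests, against 0.137% to 0.648% in the other libraries.

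**Figure D3:**
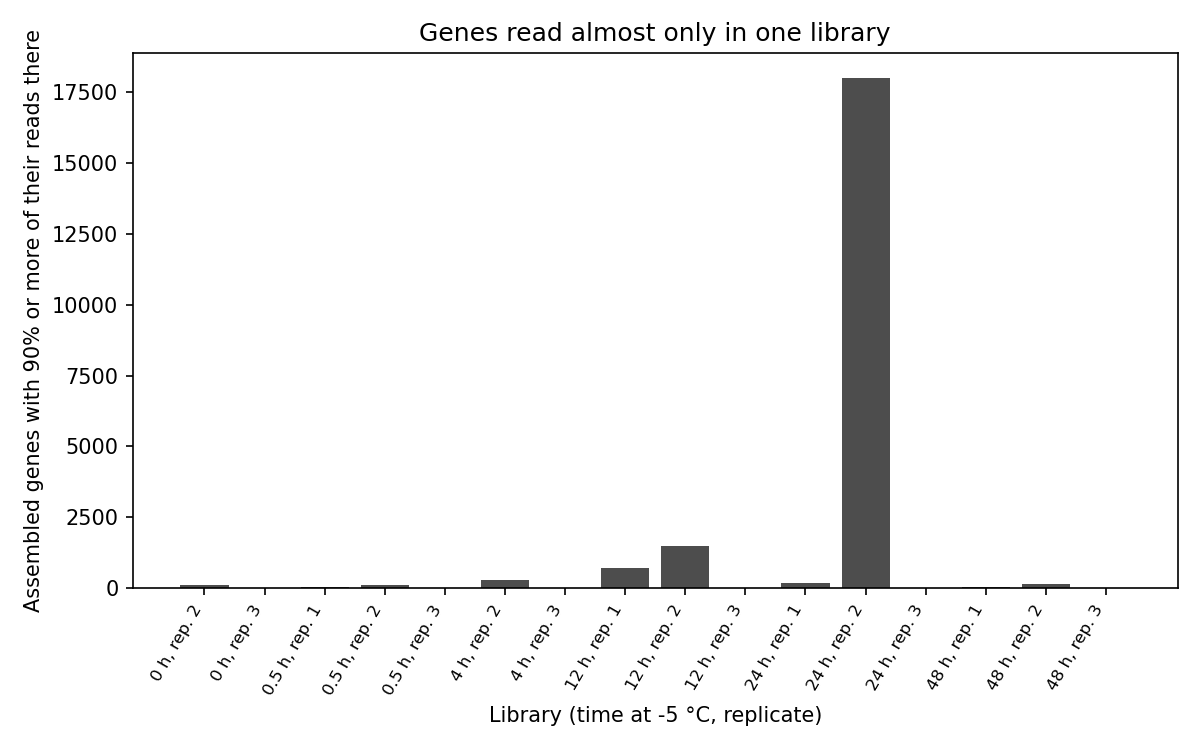
Number of assembled genes with at least 10 reads in total and 90% or more of them in 1 library (vertical axis, linear from 0), for each of the 16 libraries (horizontal axis). The bar of 24 h replicate 2 reaches 17986 and that of 12 h replicate 2, the next highest, 1475.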

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

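The tests of a daily rhythm, of depth at 48 h and of 24 h of cold were chosen only after the results were seen; the fit with library size alone was planned, and the sums over components were added. The change against 0 h differed between 4 and 12 h for 26 genes, by the direct contrast of the times, all of them higher at 12 h; without either 4 h library 0 were called.

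Among the late genes, 3 technical or timing accounts of the rise between 4 and 12 h were examined. Scaling between libraries is argued against, since 23 of the 26 genes higher at 12 h than at 4 h were also called so with library size alone. There, 13 of the 14 late genes were called higher at 24 and 48 h against 0 h, which does not test the step from 4 to 12 h. Reads moving between assembled genes of one component are argued against only for 24 and 48 h against 0 h. In those comparisons 8 of the 9 components were called higher with counts summed over components, and the step from 4 to 12 h was not tested for them. A daily rhythm with cold begun at one clock hour would return the genes towards 0 h at 24 h, but the late genes were chosen for a rise at 24 h. A daily rhythm is argued against by the 26 genes chosen on 12 h against 4 h alone. Their median log2 fold change from 12 to 24 h was 0.75 (bootstrap interval 0.566 to 0.971). That interval resamples genes, which lie in 15 components and share the same libraries. It therefore leaves out variation between libraries and between pots. A response to cold, to the move or to the time passed, and a difference between pots remain open. These cannot be told apart, as each time was 1 pot and no plants were kept warm for the same time. A cold response is therefore a hypothesis here.

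The change against 0 h also differed between 24 and 48 h, for 65 genes by the direct contrast, and for 18 of these without 24 h replicate 2. Weighed here were 5 genes with 0 reads in all 48 h libraries and at least 10 in each of the other 13. Lower depth at 48 h is argued against, since 7 of those 13 libraries had a smaller total count than the shallowest 48 h library. Only 3 of the 560 triples of libraries, the 48 h triple included, had as many genes absent from the triple alone. A triple of mixed times had 8, however, so a larger count arose without a shared time, and chance stays open. Whether other gene copies in the 48 h plants replaced them stays open: 0% had a sibling gene read only at 48 h, but random draws gave 0 as well, so the prediction that a low share would exclude this was wrong. A loss already begun by 24 h stays open too, with a median log2 fold change at 24 h of 0.13 (interval -1.01 to 1.23) over 5 genes whose choice required reads at 24 h, and pot and time cannot be told apart.

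In the library of 24 h replicate 2, 5.70% of counts fell on genes outside the tests, against at most 0.648% in any other library. Greater depth is argued against as the source of its 17986 genes, since after thinning to equal depth it still had 23.4 times as many as the next library. Cold for 24 h is argued against: of 18042 such genes chosen without use of the other 24 h libraries, those read 0.56% and 1.69%. Of the 17986, 0 h replicate 3 read 15.3%, the highest share of any other library. Added RNA of another organism or plant may be a source and stays open: over 19774 genes common to the others, its rank correlation with them was 0.884, above their range of 0.819 to 0.867 where a value within it had been predicted.

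The columns given as 0 h replicate 1 and 4 h replicate 1 were equal in 214531 of 214531 rows, and which time their values belong to was not tested.

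Other divisions of the samples were counted for 3 results. The 488 genes of the test of all times exceeded every other of 40 drawn assignments. The highest other gave 124 and only 1 of the 40, the real one, reached 488, which argues against chance division at that level. Single libraries were shuffled and each time was 1 pot, so a difference between pots could exceed the other assignments as well. For 48 h against 24 h the real division gave 65 genes and the highest other 0, with 1 of 10 as large, and 10 divisions are too few for a share under 0.05. For 24 h against 12 h the real division gave 0 and the highest other 6; with a real count of 0, all 10 of 10 had to be as large, so this count tests nothing.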

How the results depend on the processing

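The fits of the identical library, robust shrinkage and sums over components were chosen after the data were seen; the other settings were planned. The share of the 100 most abundant genes and the genes detected kept their side of the threshold under their alternatives, with permutation p from 0.83 to 0.98. Counts of genes moved with nearly every setting, and a minimum of 2-fold moved none; unless stated, the cause was not tested. In the lists that follow, values come in the order 0.5, 4, 12, 24 and 48 h against 0 h, then 4 h against 0.5 h, 12 h against 4 h, 24 h against 12 h and 48 h against 24 h. The reference counts are 4, 0, 15, 22 and 53, then 0, 26, 0 and 65, with 488 genes at any time. DESeq2 called 233, 163, 371, 367 and 1122, then 495, 551, 24 and 1660, and 3502 at any time. It left from 656 to 29470 of the tested genes without an adjusted p, depending on the comparison. It gave 10 sustained, 113 early transient, 88 late, 11 peak and 274 switched genes, with 160 shared by 24 and 48 h. Without a filter the calls were 795, 962, 1050, 2711 and 1771, then 1274, 1293, 4953 and 7007, and 15362 at any time. The patterns were then 68 sustained, 460 early transient, 158 late, 258 peak and 420 switched genes, with 456 shared. Limma on the scaled table called 167, 11, 39, 65 and 522, then 165, 53, 0 and 670, and 948 at any time, with 5 sustained, 12 early transient, 34 late and 242 switched genes and 49 shared. RLE factors gave 2 at 0.5 h. Library size alone gave 11 at 0.5 h, 34 at 48 h, 1 at 4 h against 0.5 h, 42 at 48 h against 24 h and 7 early transient genes; it moved the median log2 fold change of all genes at 0.5 h to 0.21, from 0.10 with TMM. A filter of 1 CPM in 3 libraries gave 118, and robust shrinkage 104, at 48 h against 24 h. An adjusted p under 0.01 left 0 at 0.5 h, 13 at 24 h, 18 at 48 h, 6 at 12 h against 4 h, 10 at 48 h against 24 h and 120 at any time, with 0 early transient, 8 late and 5 switched genes, since the threshold is stricter. Fits of only the times compared called 0, 0, 0, 0 and 229, then 98, 0, 0 and 563; patterns across times have no value there. Sums over components called 8 at 12 h, 8 at 24 h and 27 at 48 h, then 15 at 12 h against 4 h, 33 at 48 h against 24 h and 199 at any time, with 4 early transient, 7 late and 3 switched genes and 8 shared; fewer units were tested. All 18 libraries gave 25 at 12 h, 40 at 24 h, 124 at 48 h and 4 at 4 h against 0.5 h, with 0 early transient, 26 late and 21 switched genes and 29 shared. The identical library at 0 h alone gave 30 at 0.5 h, 34 at 12 h, 55 at 24 h, 200 at 48 h and 770 at any time, with 9 early transient, 25 late and 35 switched genes and 37 shared. At 4 h alone it gave 0 at 0.5 h, 3 at 4 h against 0.5 h, 42 at 48 h against 24 h and 0 early transient genes. Leaving out each library in turn, the calls ranged from 0 to 8 at 0.5 h, from 0 to 0 at 4 h, from 2 to 30 at 12 h, from 3 to 24 at 24 h and from 12 to 68 at 48 h. The steps ranged from 0 to 2 for 4 h against 0.5 h, 0 to 70 for 12 h against 4 h, 0 to 3 for 24 h against 12 h and 10 to 164 for 48 h against 24 h, and any time from 133 to 757. Sustained genes ranged from 0 to 0, early transient from 0 to 4, late from 0 to 16, peak from 0 to 3, switched from 2 to 14 and shared from 3 to 18. Where 0 or 4 h was left with 1 library, that library was assumed to vary like the other times.

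Replicate numbers do not pair the samples: deviations of libraries with the same number had a median correlation of -0.049 (from -0.33 to 0.37), and 1 of 16 libraries was closest to its own number. With a replicate block the calls were 0 at 0.5 h, 12 at 24 h, 26 at 48 h, 7 at 12 h against 4 h, 31 at 48 h against 24 h and 228 at any time, with 0 early transient and 7 switched genes.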

Other observations

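These counts were made after the data were examined and belong to no planned comparison. Genes with at least 10 reads in every library of a time and 0 reads in all other libraries numbered 35 at 48 h and 28 at 0.5 h, but 0 at 12 h and 0 at 24 h. Of 560 triples of libraries, 1 had as many as the 48 h triple and 2 as many as the 0.5 h triple, these triples included, and the highest triple of mixed times had 8. A sibling gene in the same assembly component that was read in at least 13 libraries was present for 42.9% of the 48 h genes and 32.1% of the 0.5 h genes, against 43.3% of all genes with at least 10 reads. For the 17986 genes concentrated in 24 h replicate 2 it was 2.71%.

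Replicates of a time also differed in single abundant genes. Of 11475 genes with a mean of at least 10 CPM, 79 had at least 100 reads in one 12 h library and at most 2 in another. The same was seen for 50 genes at 24 h, 36 at 0.5 h and 11 at 48 h.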
